A study of Mus musculus with 16 samples.

How the data were processed

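Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in nuclei of myeloid-derived suppressor cells (MDSCs) sorted from mouse bone marrow. The 16 libraries form 8 groups of 2 biological replicates: granulocytic (gMDSC) or monocytic (mMDSC) cells, from female or male C57BL/6 mice, after implantation of GL261 cells (a mouse glioma line) or a sham injection. Per the labels' protocols, each replicate combined cells of 2 mice, 160000 nuclei were tagmented for 30 min, and libraries were read as paired ends for 75 cycles. The surface markers of the sort gates are not given in the sources used here.

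The authors deposited raw read counts per region, 1 table per library over the same 89775 regions in all 16 tables, with no normalization. They also deposited 1 peak list per library. The names of the peak lists carry one date for every library numbered 1 and another for every library numbered 2. Whether these are dates of the experiment or of the file processing is not given, so whether the replicate number marks a batch is open, and each group holds 1 library of each number. In the peak lists, per the column order of the deposited narrowPeak format, each peak has a score, a fold enrichment (ratio) over local background, a −log10 p-value and a −log10 q-value, all as the authors' peak caller wrote them. Every region of the count tables overlapped a peak of at least 1 library, and 54848 (61.1%) overlapped a peak in both replicates of a group. The merged union of all peaks holds 127130 intervals, so the shared set is a selection from it, and the rule of selection is not given in the sources used here. Per the submitters' processing notes, cutadapt 1.9.1, BWA 0.7.17-r1188, SAMtools 1.10, MACS2 2.1.2, deepTools 3.2.0 and bedtools 2.17.0 were used with the mm10 build; the role of each tool, read filters, duplicate removal and any shift of reads for the Tn5 offset are not given there. Because peaks were called per library, the number of peaks depends on depth as well as on accessibility, whereas the counts were taken over 1 common set.

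Regions had a median width of 474 bp (149 to 4710 bp) and are given in mm10 coordinates counted from 1. Genes came from a RefSeq table of the matching assembly, GRCm38.p6, which gives gene bodies without strand. Transcription start sites could therefore not be placed, and the rule fixed before the data were examined (nearest start site within 50 kb) was replaced by the nearest gene body within 50000 bp, among protein-coding genes and the genes of the fixed lists. This assigned 72930 regions, 47596 of them inside a gene, and gave 16961 gene loci with a median of 3 regions, each the sum of its regions' counts. A locus value is thus the accessibility around a gene and not its expression, and a region inside 1 gene can regulate another. A region within 1000 bp of either end of a gene is called a gene-end region; it stands in for the promoter rule, as an alternative. Motif searches were not run, because they need a genome sequence.

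Regions and loci were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM scaling, filterByExpr by group) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. One model over all 16 libraries gave the cell type contrast (mMDSC minus gMDSC, averaged over sex and treatment) and its interactions. Models of the 8 libraries of 1 cell type gave tumor minus sham and male minus female, each averaged over the other factor, and their interaction. CPM were computed with TMM-scaled library sizes. Values are means ± SD over libraries, with n = 8 per cell type and n = 4 per treatment or sex within a cell type, and log2 fold changes are given ± SE. Testing was done with limma 3.58.1 for gene lists (camera with a preset correlation of 0.01, then with an estimated correlation, and fry), DESeq2 1.42.0 as the alternative tool, and exact two-sided permutation tests in scipy 1.17.1 for peak numbers. Overlaps of peaks (at least 1 bp) were found with bedtools 2.31.1.

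Before the data were examined, 20 gene lists and the rule for named genes were fixed. The lists were monocyte markers, granulocyte markers, primary granule and progenitor genes, integrins, other cell adhesion genes, suppressive function genes, chemokines and their receptors, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, MHC class II and antigen presentation, glucocorticoid-responsive genes, AP-1 and early response genes, cell cycle genes and sex-linked genes, plus markers of B cells, of T and NK cells, of erythroid cells and megakaryocytes, of eosinophils, basophils and mast cells, of dendritic cells, and of stromal and endothelial cells. Of their 344 genes, 343 matched the annotation and 329 had a locus. The rule named, per comparison, the 5 loci with the largest change in each direction whose groups did not overlap, up to 4 called members of each list with the smallest p (at most 2 with none called), 13 fixed genes, and 5 sex-linked genes in the sex comparisons. For regions it named the 3 largest changes in each direction.

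Total counts over the regions were 7609140 to 13278835 per library. They hold reads in regions only and are not sequencing depth. The common biological coefficient of variation was 0.127 in mMDSC and 0.140 in gMDSC regions, and 0.0756 and 0.0875 in loci. The tests of cell type, and of tumor and sex within each cell type, were first run on simulated counts. These were drawn from the real means and totals with 200 features changed by known folds, 50 per fold. Libraries were drawn independently, without structure shared between them, and interactions and tumor tests within 1 sex were not simulated. For tumor against sham in mMDSC, 24% of regions changed 1.5-fold, 68% of those changed 2-fold and 92% of those changed 4-fold were recovered, and in gMDSC 28%, 40% and 92%. At the level of loci, recovery at 1.25-fold, 1.5-fold and 2-fold was 54%, 78% and 94% in mMDSC and 44%, 74% and 82% in gMDSC. Counting intervals, and floors of 3 counts summed over a group, cover counting error only, because reads without molecular identifiers are not independent molecules.

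Alternatives fixed before the data were examined were DESeq2, size factors by DESeq2's rule within edgeR, library totals without scaling, no filter on low counts, the replicate number as a block, each library left out in turn, libraries of 1 replicate number alone, all 16 libraries in 1 model, gene-end regions, other list tests, and a stricter peak threshold (−log10 q of at least 5) and overlap (50% reciprocal). Loess offsets against intensity, thinning to the smallest total, a block of replicate number within sex, sums of libraries by sex and number, and the test of the sex difference between cell types were added after seeing the data.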

Results

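Open chromatin was profiled in granulocytic and monocytic myeloid-derived suppressor cells, immature myeloid cells that restrain T cell responses in tumors, from bone marrow of mice with or without an intracranial GL261 glioma. The series sets the subsets against each other with an interest in cell adhesion, and its 8 groups cross cell type, sex and treatment with 2 replicates each. Total counts over the 89775 regions averaged 8502283 ± 778888 in gMDSC and 11301938 ± 1351738 in mMDSC libraries (SD, n = 8 each). Across regions, log2 CPM of replicate pairs correlated at 0.939 to 0.962, that of libraries of the same cell type in other groups at 0.931 to 0.970, and that of libraries of different cell types at 0.769 to 0.861. Regions are not independent replicates, so these values describe similarity only. Counts of every replicate pair differed by more than sampling noise (chi-square over degrees of freedom 1.88 to 3.55), which argues against copies of one library but does not show that the libraries are independent. Replicates were taken from the labels.

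The first principal component of region accessibility held 60.2% of the variance and separated the cell types. Along the second, with 6.62%, all female libraries lay between 19.9 and 47.6 and all male libraries between -78.0 and 4.3, while sham and tumor libraries overlapped.

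**Figure D1:**
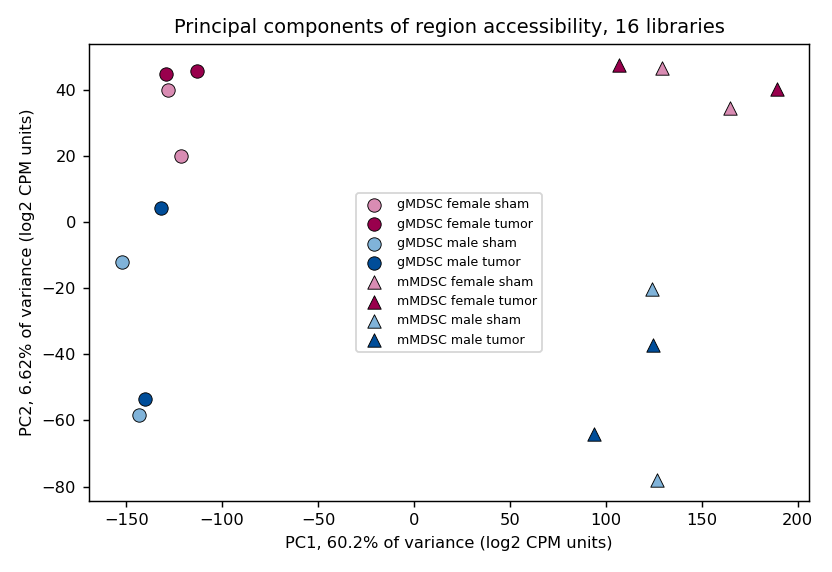
Scores of the 16 libraries on the first 2 principal components of log2 CPM over regions, with symbols for cell type and colors for sex and treatment. The horizontal axis (60.2% of variance) separates gMDSC from mMDSC, and on the vertical axis (6.62%) female libraries lie between 19.9 and 47.6 and male libraries between -78.0 and 4.3.

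The comparison of cell types asked how the chromatin of monocytic and granulocytic MDSCs differs. Mafb, Irf8, Klf4 and Mrc1 loci were more accessible in mMDSC. Mafb, a regulator of monocyte and macrophage differentiation, had 160 ± 16.5 CPM in mMDSC against 33.0 ± 7.47 in gMDSC (SD, n = 8 each; log2 fold change 2.29 ± 0.0979), and Irf8, which directs progenitors toward monocytes, had 104 ± 9.08 against 37.1 ± 5.30 (adjusted p = 1.7e-14). Klf4 (1.24) and Mrc1, the mannose receptor gene (1.08), were also higher. Retnlg and Cxcr2 lay the other way: Retnlg, a resistin-like protein of neutrophils, had 70.1 ± 7.64 CPM in mMDSC against 364 ± 45.4 in gMDSC (-2.38 ± 0.0743), and Cxcr2, the neutrophil chemokine receptor gene, had 43.2 ± 7.90 against 116 ± 7.55 (-1.43 ± 0.0835). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 60748 of 89584 regions differed, 30722 higher and 30026 lower in mMDSC, of which 13934 and 9766 changed at least 2-fold. Within sham libraries 49530 regions differed and within tumor libraries 47466. At the level of loci, 12152 of 16950 differed, 6147 higher and 6005 lower, and with library totals in place of TMM scaling 7199 were higher and 5048 lower.

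The largest locus changes toward mMDSC were Psma4 (log2 fold change 3.18), S100b (3.06), Olfr283 (3.05), Drp2 (3.01) and Klk1b21 (2.93). Toward gMDSC they were Cstdc4 (-2.88) and Stfa2l1 (-2.78), both of the stefin family of protease inhibitors, Trim60 (-2.38), Retnlg (-2.38) and Mis12 (-2.35). Most of these loci rest on few regions. Psma4, S100b, Stfa2l1, Trim60 and Mis12 hold 1 region each, and Olfr283, Drp2 and Klk1b21 hold 2 each, while Cstdc4 and Retnlg hold 6 each. Psma4 and Drp2 were near the floor in gMDSC libraries, with at most 2.97 and 2.93 CPM. Among single regions, chr10:13539874-13540250 inside Pex3 rose most in mMDSC, with 13.3 ± 2.01 CPM against 0.959 ± 0.526 (SD, n = 8 each; 3.77). It was followed by chr1:167004670-167005034 inside Fam78b (3.72) and chr9:39634065-39634304, which lies 10019 bp from Olfr960 (3.70). Toward gMDSC, chr16:48875296-48875731, 1015 bp from Retnlg, changed by -4.18, chr16:36183944-36184584 in Cstdc4 by -4.04, and chr2:129364040-129364757, 171 bp from Il1b, the interleukin-1 beta gene, by -3.89 (1.38 ± 0.755 against 19.5 ± 3.96 CPM). Gene-end regions made up 8.05% of the regions at least 2-fold higher in mMDSC and 3.64% of those at least 2-fold higher in gMDSC, against 21.8% of regions called with a smaller change and 17.4% of regions with no called difference.

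Of 20 monocyte markers, 14 were higher and 3 lower in mMDSC (14 and 3 adjusted over the list alone; camera adjusted p = 8.29e-05, adjusted p = 0.323 with an estimated correlation). Ly6c2, which encodes the monocyte antigen Ly6C, changed little (0.18, adjusted p = 0.0130), whereas Ccr2 (0.67) and Csf1r (0.66, but -0.0099 at its gene-end region), receptors for monocyte chemokines and growth factor, were higher. Of 20 granulocyte markers, none was higher and 16 were lower (0 and 17 adjusted over the list alone; camera adjusted p = 2.14e-06, adjusted p = 0.323 with an estimated correlation). Lower were Hdc (-1.10), Il1r2 (-1.05) and Ly6g, the antigen commonly used to define granulocytic MDSCs (-0.79). Primary granule and progenitor genes split, with 6 of 10 higher and 3 lower (the same counts adjusted over the list alone; camera adjusted p = 0.405, adjusted p = 0.638 with an estimated correlation). Ctsg (1.54), Sox4 (0.89) and Flt3 (0.76) were higher and Cd34 lower (-0.82), although Cd34 was higher at its gene-end region (0.79). Of 20 cell cycle genes, 19 were higher with none lower (19 and 0 adjusted over the list alone; camera adjusted p = 0.00715, adjusted p = 0.167 with an estimated correlation). Rrm2 (0.79), Ccne2 (0.54), Mcm6 (0.68) and Cdk1 (0.62) were among them.

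**Figure D2:**
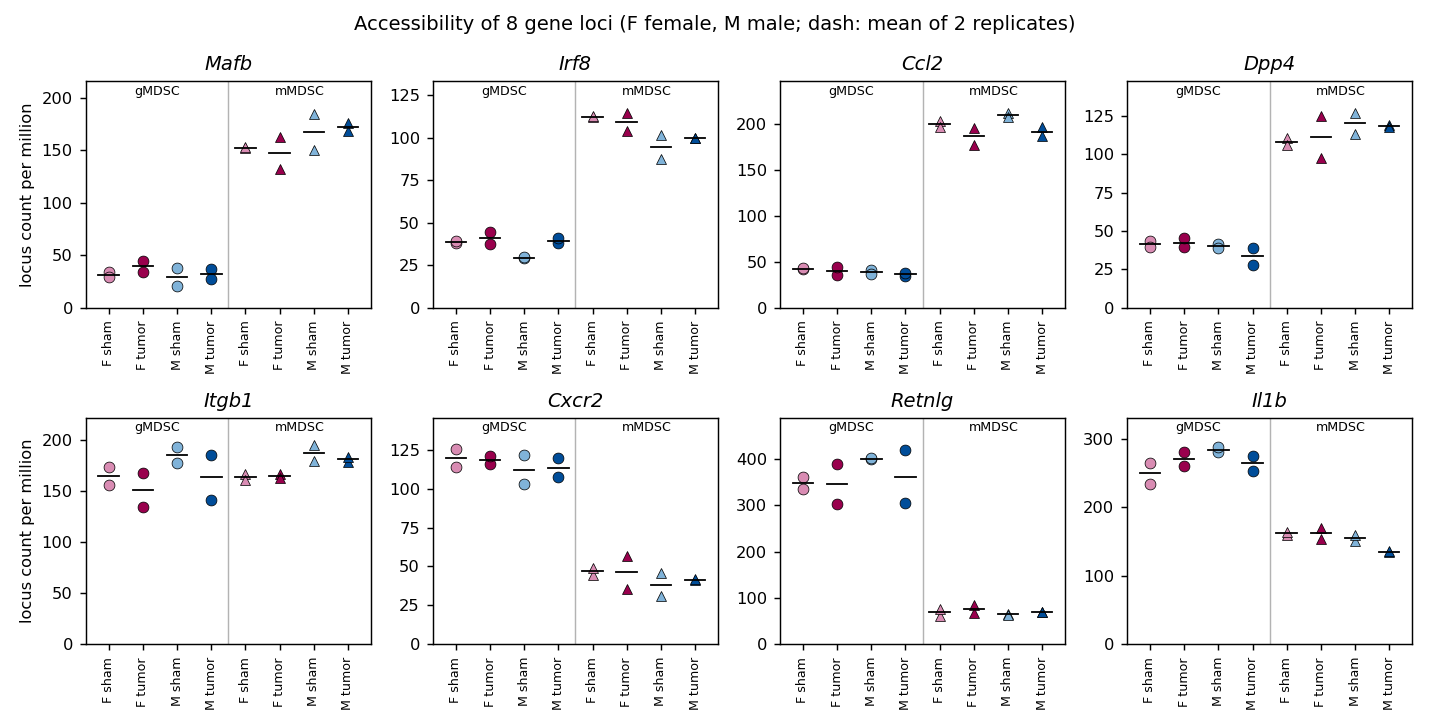
CPM of 8 gene loci in each library, by cell type, sex (F, M) and treatment; points are libraries and dashes are means of 2 replicates. Mafb, Irf8, Ccl2 and Dpp4 lie higher in mMDSC, Cxcr2, Retnlg and Il1b lie higher in gMDSC, and Itgb1 overlaps between the cell types (174 ± 12.0 CPM in mMDSC and 166 ± 20.6 in gMDSC, n = 8 each).

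Adhesion genes changed in both directions. Of 25 integrin loci, 10 were higher and 8 lower in mMDSC (11 and 8 adjusted over the list alone; camera adjusted p = 0.530). Itga3 (log2 fold change 2.09), Itga5 (0.82) and Itgb8 (0.81) were higher and Itga8 was lower (-0.71). Itgb1, the common beta-1 integrin chain, did not pass at its locus (174 ± 12.0 CPM against 166 ± 20.6, SD, n = 8, log2 fold change 0.07, adjusted p = 0.282). Its locus value sums regions that changed both ways, since 3 of its 12 regions were called higher and 5 lower in mMDSC. Its gene-end region chr8:128685125-128686601 was higher (65.7 ± 5.89 against 57.3 ± 7.65 CPM, log2 fold change 0.20, adjusted p = 0.00364). Of 30 other adhesion genes, 16 were higher and 11 lower (16 and 11 adjusted over the list alone; camera adjusted p = 0.288). Dpp4, the gene of the surface peptidase CD26, had 115 ± 9.80 CPM in mMDSC against 39.3 ± 5.25 in gMDSC (1.55 ± 0.0678), with the same direction at its gene-end region chr2:62411110-62412632 (27.9 ± 4.78 against 10.4 ± 1.68; 1.43). The cadherin gene Cdh1 was higher (73.5 ± 3.42 against 29.4 ± 3.06; 1.32), and Thbs1, which encodes the matrix protein thrombospondin 1, was lower (-0.92).

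Genes of suppressive function were mostly less accessible in mMDSC: 7 of 24 were higher and 15 lower (7 and 16 adjusted over the list alone; camera adjusted p = 0.0111, adjusted p = 0.380 with an estimated correlation). Slc7a11, a cystine transporter, fell most (-1.50), and Arg2 (-1.01), Nt5e (-0.92), Vegfa (-0.74), Cd274, the PD-L1 gene (-0.75), S100a8 (-0.94) and S100a9 (109 ± 24.9 against 217 ± 17.5 CPM) were lower, while Arg1 was higher (0.77). Nos2 was lower by a small margin (-0.25, adjusted p = 0.0227), a call that ended without gMDSC female sham 1, gMDSC male sham 2, mMDSC female sham 1, mMDSC female tumor 1, mMDSC male sham 1 or mMDSC male tumor 1 (log2 fold change -0.24 to -0.17, adjusted p = 0.0510 to 0.0828) and turned to 1.08 at its gene-end region. Inflammatory cytokine and NF-kB target genes had 6 of 20 higher and 12 lower (6 and 12 adjusted over the list alone; camera adjusted p = 0.00715, adjusted p = 0.380 with an estimated correlation), with Il1b at 154 ± 12.7 against 267 ± 17.6 CPM (-0.80) and lower Il1rn (-1.23), Osm (-0.98) and Cxcl2 (-1.31). Chemokine genes changed both ways, 11 of 20 higher and 6 lower (11 and 6 adjusted over the list alone; camera adjusted p = 0.405). Ccl2, whose product attracts monocytes, rose from 39.3 ± 3.49 CPM in gMDSC to 196 ± 11.0 in mMDSC (2.32, adjusted p = 4.6e-17), whereas Cxcl1 (-1.14) and Cxcl3 (-1.11), which encode neutrophil chemoattractants, were lower.

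Antigen presentation genes were higher in mMDSC, 10 of 14 with 2 lower (10 and 2 adjusted over the list alone), including Cd40 (1.63), Ciita, the master regulator of MHC class II genes (1.51), Ctss (1.31) and H2-DMb2 (1.03). As a list this result was marginal (camera adjusted p = 0.0497, adjusted p = 0.638 with an estimated correlation), and it was lost without any one of gMDSC female sham 1, gMDSC female tumor 1, gMDSC male sham 1, gMDSC male tumor 1, mMDSC female sham 1, mMDSC female tumor 2, mMDSC male sham 2 or mMDSC male tumor 2 (adjusted p = 0.0551 to 0.0658). Interferon-stimulated genes were split evenly, 8 of 22 higher and 8 lower (8 and 8 adjusted over the list alone; camera adjusted p = 0.894), with Mx1 (35.3 ± 1.71 against 9.57 ± 1.75 CPM) and Mx2 (1.68) higher and Rtp4 (-1.27) and Stat1 (-0.46) lower. Glucocorticoid-responsive genes had 5 of 15 higher and 7 lower (5 and 7 adjusted over the list alone; camera adjusted p = 0.398), among them Sgk1 (-0.51), Zbtb16 (-0.48) and Cd163 (-0.48). Of 20 AP-1 and early response genes, 6 were higher and 12 lower (6 and 12 adjusted over the list alone; camera adjusted p = 0.196), with Nr4a2 (0.84) and Batf3 (0.58) higher and Klf6 (-0.78) and Egr3 (-0.69) lower.

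Markers of other cell types that a bone marrow sort could hold moved as follows. Dendritic cell markers had 8 of 12 higher and 4 lower in mMDSC (8 and 4 adjusted over the list alone; camera adjusted p = 0.0713), with Siglech (38.4 ± 3.78 against 10.3 ± 0.808 CPM), Ccr9 (1.32) and Xcr1 (0.96) higher. Stromal and endothelial markers had 9 of 12 higher and 3 lower (9 and 3 adjusted over the list alone; camera adjusted p = 0.0367, adjusted p = 0.323 with an estimated correlation, and 0.0510 without mMDSC female tumor 2), with Cxcl12 (1.43) and Sparc (1.21) higher and Col1a1 lower (-0.85). B cell markers had 3 of 12 higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.808), with Blnk (1.39) and Ms4a1 (1.03) higher and Ebf1 lower (-0.80, but 0.49 at its gene-end region). T and NK cell markers had 6 of 12 higher and 5 lower (6 and 5 adjusted over the list alone; camera adjusted p = 0.852), with Bcl11b (2.36) and Cd4 (1.27) higher and Ncr1 lower (-0.73). Erythroid and megakaryocyte markers had 3 of 15 higher and 5 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.917), with Ermap (1.29) and Gata1 (1.29) higher. Eosinophil, basophil and mast cell markers had 4 of 12 higher and 3 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.808), with Alox15 higher (0.80) and Siglecf lower (-0.34). Bcl11b, Ermap and Gata1 hold 1 region each, and Bcl11b and Gata1 had at most 1.68 and 3.10 CPM in gMDSC libraries. The median of the erythroid list was -0.0699 while camera placed it upward, and the median of the eosinophil list was 0.0965 while its mean was -0.0437 and camera placed it downward. Of the 12 sex-linked genes, 2 were higher and 3 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.808). No list kept its call with an estimated correlation, while fry, which tests the members of a list without setting them against other loci, called 16 lists. Among these were lists that changed both ways, such as integrins (10 higher, 8 lower, fry adjusted p = 0.00144). With 12152 of 16950 loci called, fry calls do not show that the members of a list moved together.

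Peak lists carried the same contrast. The authors' lists held 52717 ± 6653 peaks in mMDSC and 35314 ± 4381 in gMDSC (SD, n = 8 each; exact two-sided permutation p = 0.000155, the smallest this design allows, adjusted p = 0.000777 over 5 comparisons). Peaks covered 28.5 ± 3.11 Mb in mMDSC and 19.3 ± 2.34 Mb in gMDSC. Within libraries of 1 replicate number the difference was 20809 peaks (number 1) and 13997 (number 2), each with an exact p of 0.0286, the smallest for 4 against 4. Peaks were called per library and the mMDSC totals over regions were larger, so these totals and cell type were not separated in this count. Tumor and sham libraries differed by less than their spread in both cell types (exact p = 0.886 each). Female mMDSC libraries had 57413 ± 4558 peaks and male ones 48021 ± 4868 (n = 4 each; exact p = 0.0857, adjusted p = 0.214), and under the stricter peak threshold the exact p was 0.0286. Every female mMDSC library had a larger total over regions (11286806 or more) than every male one (10977182 or less), so these totals and sex were not separated in this count either. In gMDSC the sexes differed less (exact p = 0.571). Replicate pairs shared 74.5% of peaks, libraries of other treatment 75.2% and of other sex 74.0%. On average 76.2% of gMDSC peaks overlapped a peak of an mMDSC library, while 51.0% of mMDSC peaks overlapped one of a gMDSC library. Of the regions, 3576 overlapped a peak in all 8 mMDSC libraries and in no gMDSC library, and 69 the reverse. These overlaps also depend on the longer peak lists and larger totals of mMDSC. By counts over the common regions, 13934 were at least 2-fold higher in mMDSC and 9766 in gMDSC.

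**Figure D3:**
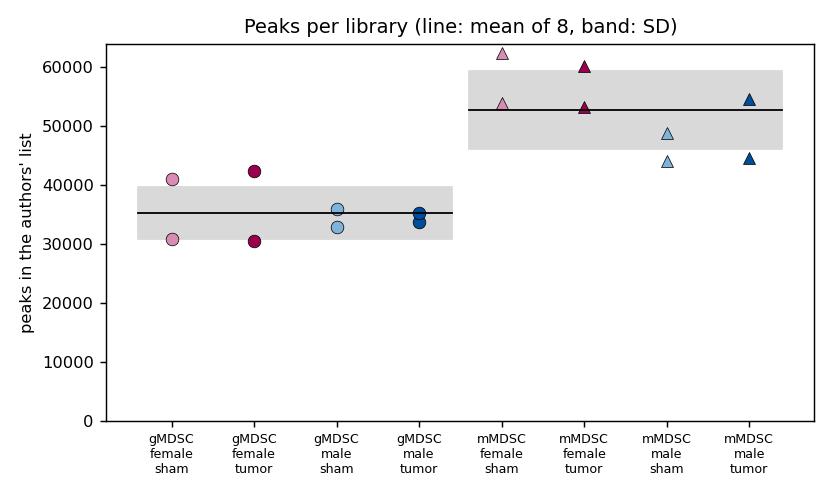
Number of peaks in the authors' list of each library (points), by group, with the mean of 8 libraries per cell type (line) and its SD (band). All mMDSC libraries lie above all gMDSC libraries, at means of 52717 and 35314 peaks.

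The tumor comparison asked whether an intracranial glioma alters chromatin of marrow MDSCs. In mMDSC, the adhesion genes of interest did not move: Dpp4 changed by 0.01 (log2, 95% interval -0.154 to 0.176) and Itgb1 by -0.02 (-0.125 to 0.0913). Monocyte genes Ccr2 (-0.13) and Csf1r (-0.10) and the inflammatory gene Il1b (-0.10) did not pass either. The smallest p among listed genes was that of Gata2, a factor of basophil and mast cell development, with 38.6 ± 3.44 CPM in tumor and 30.7 ± 3.10 in sham libraries (SD, n = 4 each; 0.34, unadjusted p = 0.00294, adjusted p = 1). By edgeR 0 of 87971 regions and 0 loci passed, and DESeq2 called 0 of either. At an unadjusted p under 0.05 by edgeR lay 1939 regions and 276 loci, where chance alone would give 4398.55 and 843.05. With fewer than that, the test was conservative on these data, and recovery in simulated counts may not carry over. With the replicate number as a block 1 region passed, and with it as a block within each sex, a fit added after seeing the data, 12 regions and 0 loci did. Libraries numbered 1 alone gave 13 regions and those numbered 2 alone gave 9. Without mMDSC male sham 2, 2 regions were called. Within females no region passed, but 9 did without mMDSC female sham 2 and 8 without mMDSC female tumor 2. The median 95% interval was ± 0.410 for a region and ± 0.182 for a locus, each for 1 feature without adjustment. Changes well below these sizes were not detectable, and larger ones could be missed after adjustment. In simulated counts 24% of regions changed 1.5-fold and 68% of those changed 2-fold were recovered.

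As lists, eosinophil, basophil and mast cell markers lay higher in tumor mMDSC (camera adjusted p = 0.00642, adjusted p = 0.589 with an estimated correlation), with 0 of 12 members called over all loci and 1, Gata2, adjusted over the list alone. The call was lost without mMDSC female tumor 1 (adjusted p = 0.0827) or mMDSC male tumor 1 (0.143). Sex-linked genes lay lower (camera adjusted p = 0.00642, 0.696 with an estimated correlation), again with 0 of 12 members called. That call rested on Y-linked loci near 0 counts in females and was lost without mMDSC female sham 1 (0.657), mMDSC female tumor 2 (0.466), mMDSC male sham 1 (0.0695) or mMDSC male tumor 1 (0.0695). Other lists became called with a library left out: granulocyte markers without mMDSC female sham 2 (0.0424), mMDSC female tumor 1 (1.12e-08) and, in the opposite direction, mMDSC female tumor 2 (0.0230), and monocyte markers without mMDSC male sham 1 (4.75e-06), mMDSC female tumor 2 (0.0103) or mMDSC male tumor 2 (0.00588). The same held for antigen presentation genes without mMDSC female sham 2 (0.0424), mMDSC male sham 1 (0.000151) or mMDSC male tumor 2 (0.0327), and for inflammatory genes without mMDSC female tumor 2 (0.0334) or mMDSC male sham 1 (0.00680). Chemokine genes (0.0103) and suppressive function genes (0.0377) were called without mMDSC female tumor 2, primary granule genes without mMDSC female sham 1 (0.0422) and erythroid markers without mMDSC female tumor 1 (0.0242).

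In gMDSC, Thbs1 had the smallest unadjusted p for tumor among listed genes, with 185 ± 11.5 CPM in tumor against 147 ± 11.4 in sham libraries (SD, n = 4 each; log2 fold change 0.34 ± 0.0639, unadjusted p = 8.52e-05). It did not pass over all loci (adjusted p = 1) and was the only one of 30 other adhesion genes past the threshold adjusted over the list alone (1 higher, 0 lower). Larger changes with larger p were seen at Gata1 (1.06, unadjusted p = 0.0431) and Oas1a (0.55, 0.0144). Irf7, an interferon regulator, changed by 0.25 (unadjusted p = 0.00533), Padi4 by 0.20, Itgb1 by -0.15 and Dpp4 by -0.11, none past adjustment. By edgeR 0 of 87231 regions and 0 loci passed, and by DESeq2 0 of either. At an unadjusted p under 0.05 by edgeR lay 2423 regions and 286 loci, again fewer than the 4361.55 and 841.95 that chance alone would give. The block by replicate number gave 1 region, the block within each sex 4 regions and 9 loci, libraries numbered 1 alone 20 regions and those numbered 2 alone 0. Without gMDSC female sham 2, gMDSC female tumor 1 or gMDSC female tumor 2, 1 region passed each time. Within males 1 region was called by edgeR and by DESeq2, chr15:39172839-39174610, 24562 bp from Rims2, with 37.1 ± 1.26 CPM in tumor against 17.7 ± 0.00346 in sham libraries (n = 2 each; 1.09, adjusted p = 0.0287); the count fell to 0 without gMDSC male sham 1, gMDSC male sham 2 or gMDSC male tumor 2. Monocyte markers as a list lay higher in tumor gMDSC (camera adjusted p = 0.0352, adjusted p = 0.540 with an estimated correlation, 0 of 20 members called), a call lost without gMDSC female sham 1 (0.205), gMDSC female tumor 2 (0.525), gMDSC male sham 1 (0.444), gMDSC male tumor 1 (0.120) or gMDSC male tumor 2 (0.121). Interferon-stimulated genes became called without gMDSC female sham 2 (0.0133) or gMDSC female tumor 1 (2.63e-05), suppressive function genes without gMDSC female tumor 1 (0.0490) and granulocyte markers without gMDSC male sham 2 (0.00806).

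Tests of whether the tumor response differed between groups gave no region. For cell type by treatment, 0 of 89584 regions and 0 loci passed by edgeR, and 0 of either by DESeq2. At an unadjusted p under 0.05 by edgeR lay 2463 regions and 292 loci, where chance alone would give 4479.2 and 847.5. Thbs1 had the smallest p among listed genes (-0.33, unadjusted p = 0.00259). Monocyte markers as a list lay lower (camera adjusted p = 0.000704, median -0.106), a call lost with an estimated correlation (adjusted p = 0.617) and without mMDSC male sham 2 (0.398). In the same comparison, interferon-stimulated genes became called without gMDSC female sham 2 (0.0310) or gMDSC female tumor 1 (0.000652), eosinophil, basophil and mast cell markers without gMDSC female tumor 1 (0.0220), granulocyte markers without mMDSC female tumor 1 (0.00832) and antigen presentation genes without mMDSC male sham 1 (0.0277). For sex by treatment, 0 regions passed in mMDSC and 0 in gMDSC by edgeR, and 0 in each by DESeq2. At an unadjusted p under 0.05 by edgeR lay 1354 and 2604, where chance alone would give 4398.55 and 4361.55. However, 1 region was called in mMDSC without female tumor 1 and 1 in gMDSC without male tumor 1.

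The sex comparison, male minus female within each cell type, was led by sex chromosome genes in both. Y-linked loci were open in males: Ddx3y had 47.4 ± 6.83 CPM in male and 0.0880 ± 0.176 in female mMDSC (SD, n = 4 each; 1795 and 4 counts), and 77.5 ± 8.24 against 0.128 ± 0.148 in gMDSC. Uty had 61.0 ± 6.39 against 0.444 ± 0.648 CPM in mMDSC and 92.1 ± 9.83 against 0.141 ± 0.163 in gMDSC. Eif2s3y had 29.6 ± 2.67 against 0.308 ± 0.616 CPM in mMDSC, and in gMDSC, with 2 female counts, its ratio was 651 (95% counting interval 180 to 5380). Usp9y in mMDSC, also with 2 female counts, had a ratio of 263 (72.5 to 2180). In gMDSC it had 56 male and 4 female counts and a ratio of 14.9 (5.5 to 56.5). H2al2b had 0 female counts and was at least 33.0-fold higher in male mMDSC and at least 55.3-fold higher in male gMDSC, against a floor of 3 counts over the group. Kdm5d differed less (3.02 in mMDSC and 2.92 in gMDSC), with 68 and 51 counts in females. The largest region differences also lay on Y. In mMDSC, chrY:142739-143141 and chrY:140581-140854 had 0 female counts, at least 299-fold and 230-fold below males, and chrY:260731-261603 had 1 (ratio 1510, 271 to 59900). In gMDSC, chrY:1285438-1286884 in Ddx3y was at least 605-fold higher in males, and chrY:1244605-1246220 and chrY:1115673-1116712 in Uty at least 404-fold and 386-fold.

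On the X chromosome, the loci of Xist, the RNA that silences one X in female cells, fell in males from 80.5 ± 6.82 to 16.4 ± 1.32 CPM in mMDSC (-2.30) and from 100 ± 7.14 to 14.6 ± 2.87 in gMDSC (-2.80). Pls3 (-2.31 and -2.46, but 0.0812 at its gene-end region in mMDSC) and Cdr1 (-1.33 and -1.85) were lower in males in both cell types, the former mainly through regions that lie in the neighboring 4933407K13Rik. The Cdr1 call was lost in mMDSC without female sham 1 (adjusted p = 0.0894), female sham 2 (0.0655), male tumor 1 (0.133) or male tumor 2 (0.0652), and in gMDSC without female sham 1 (0.144), female tumor 2 (0.0841), male sham 1 (0.0594), male sham 2 (0.261) or male tumor 1 (0.209). Btbd35f22 (-1.68) and Btbd35f8 (-1.44) were lower in male gMDSC, and Tma7-ps (-0.96) and the autosomal Olfr49 (-0.94) in male mMDSC. Of the 8 fits that leave out 1 mMDSC library, 2 called Tma7-ps and 1 called Olfr49 (highest adjusted p = 0.187 and 0.179 by edgeR). The most reduced X regions lay in 3 long non-coding RNA genes, Firre, 4933407K13Rik and Xist, which held 38 of the regions lower in males in each cell type, while 62 others in mMDSC and 56 in gMDSC lay elsewhere on X. In Firre (chrX:50563120-50635321), 19 of 21 regions were lower in male mMDSC and 20 in male gMDSC, with median log2 fold changes of -3.42 and -3.29. In 4933407K13Rik (chrX:75725458-75764699), also known as Dxz4, 16 and 15 of 17 regions were lower (-3.30 and -3.02), and in Xist (chrX:103460373-103483233) all 3 were (-4.11 and -3.48). For example, chrX:50602384-50603169 in Firre had 1.64 ± 0.209 CPM in male and 23.4 ± 0.828 in female mMDSC, and chrX:103481197-103482360 in Xist 2.05 ± 0.741 against 45.4 ± 5.08. Named largest by the rule were also chrX:50622932-50623378 (-4.61 in mMDSC, -4.27 in gMDSC), chrX:50590812-50591164 (-4.32 in mMDSC) and chrX:50565039-50565878 (-4.66 in gMDSC), all within Firre. These 3 genes were singled out after their values were seen.

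**Figure D4:**
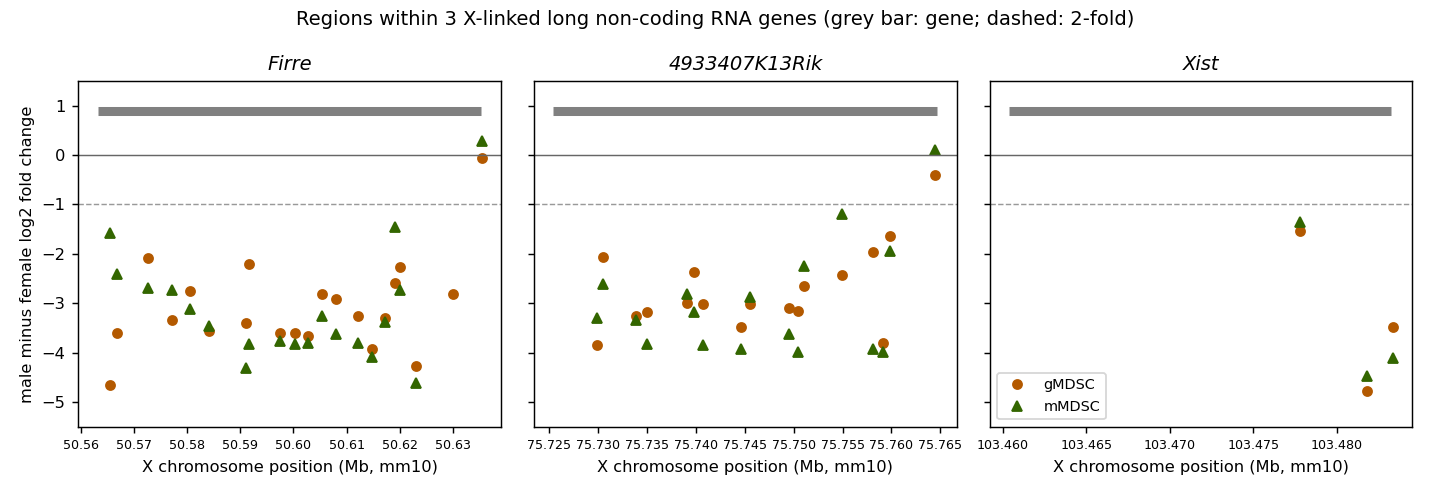
Male minus female log2 fold change of each region (points) within Firre, 4933407K13Rik and Xist on the X chromosome (mm10, Mb), in gMDSC and mMDSC; grey bars mark the genes and the dashed line a 2-fold difference. Most regions lie below the dashed line in both cell types, with medians of -3.42 and -3.29 in Firre, -3.30 and -3.02 in 4933407K13Rik and -4.11 and -3.48 in Xist (mMDSC and gMDSC).

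In gMDSC, sex differences were few outside the sex chromosomes. By edgeR 227 of 87231 regions differed, 108 higher and 119 lower in males; 79 were on Y, all higher, 94 on X, all lower, 4 on unplaced or mitochondrial sequence, and 50 on autosomes (29 higher, 21 lower). Of 16839 loci, 36 differed (15 higher, 21 lower). The count of regions rose to 1136 without gMDSC male tumor 2, 925 of them autosomal, and loci to 366; for other libraries it lay between 169 and 323. Autosomal calls numbered 99 without female sham 1, 23 without female sham 2, 154 without female tumor 1, 14 without male sham 1, 22 without male sham 2 and 17 without male tumor 1. With the replicate number as a block 356 regions were called, with libraries numbered 1 alone 5968 and with those numbered 2 alone 180. In every fit that left out 1 library, 12 autosomal, 60 X and 76 Y regions were called. Among lists, sex-linked genes were called (4 higher and 7 lower of 12, 4 and 8 adjusted over the list alone; camera adjusted p = 2.84e-05, adjusted p = 0.760 with an estimated correlation). Lists of interferon-stimulated genes (0.0369), MHC class II genes (0.0307) and erythroid markers (0.0299) passed by camera with no member called, and none did with an estimated correlation (adjusted p = 0.760 or higher). Each of these 3 lists lost its call without gMDSC female sham 2 (0.310, 0.113 and 0.260), gMDSC female tumor 2 (0.680, 0.187 and 0.317) or gMDSC male sham 2 (0.0540, 0.0505 and 0.0505); without gMDSC male sham 1 the first 2 lost theirs (0.0561 each), without gMDSC male tumor 1 the last 2 (0.104 and 0.0601), and without gMDSC male tumor 2 the first (0.147).

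In mMDSC, Thbs1, F13a1, Ccl6 and Nlrp3 were among loci less accessible in males. Thbs1 had 72.0 ± 4.56 CPM in male and 106 ± 7.98 in female libraries (SD, n = 4 each; log2 fold change -0.55 ± 0.0688, adjusted p = 0.00156) and was called in each of the 8 fits that leave out 1 library. The coagulation factor gene F13a1, a monocyte marker, had 55.5 ± 9.47 against 87.0 ± 10.6 (-0.64, adjusted p = 0.0191), the chemokine gene Ccl6 had 65.6 ± 10.3 against 97.2 ± 6.47 (-0.56, adjusted p = 0.0136) and the inflammasome gene Nlrp3 had 111 ± 14.9 against 148 ± 2.85 (-0.42, adjusted p = 0.0191). By edgeR 1127 of 87971 regions differed, 459 higher and 668 lower in males: 81 on Y (all higher), 102 on X (2 higher, 100 lower) and 944 on autosomes (376 higher, 568 lower). Of 16861 loci, 1280 differed (402 higher, 878 lower). An excess of lower calls stayed with DESeq2's size factors (loci 417 higher and 745 lower, regions 435 and 712) and with counts thinned to equal totals (loci 342 and 632, autosomal regions 329 and 578). It was smaller with library totals (loci 413 and 534) and with loess offsets (loci 383 and 421, autosomal regions 453 and 461). Among autosomal regions, more were higher without female sham 1 (129 higher, 83 lower), female sham 2 (130, 105), male sham 1 (96, 65) or male tumor 1 (43, 29). More were lower without female tumor 1 (460, 542), female tumor 2 (708, 711), male sham 2 (1231, 3783) or male tumor 2 (188, 455). Sums by sex and number gave 80 higher and 85 lower. Total counts over the regions separated the sexes completely, all male totals (8850868 to 10977182) lying below all female ones (11286806 to 13278835). After thinning, 907 autosomal regions were called, 628 of them among the 944. DESeq2 called 419 regions and 1237 loci, and with the replicate number as a block edgeR called 4293 regions and 3425 loci. Sums by sex and number gave 310 regions, 165 of them autosomal, and 29 loci. Libraries numbered 1 alone gave 6742 regions and those numbered 2 alone 2137. These counts depended on single libraries. Regions numbered 351 without mMDSC female sham 1, 391 without female sham 2, 308 without male sham 1, 207 without male tumor 1 and 5290 without male sham 2, against 1173, 1612 and 810 without female tumor 1, female tumor 2 and male tumor 2. Loci numbered 47, 29, 384, 233, 4799, 27 and 71 without female sham 1, female sham 2, female tumor 2, male sham 1, male sham 2, male tumor 1 and male tumor 2. In every fit that left out 1 library, 57 autosomal, 55 X and 76 Y regions were called, so the autosomal genes named here and below hold for all 8 libraries together, and apart from Thbs1 none of them was called in every fit.

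By list, monocyte markers had 0 higher and 5 lower of 20 in male mMDSC (0 and 12 adjusted over the list alone; camera adjusted p = 2.86e-05, lost with an estimated correlation at 0.430 and by fry at 0.0623). Among them were F13a1, Ly86 (log2 fold change -0.60), Fcgr1 (-0.39) and Fn1 (-0.30). Antigen presentation genes had 0 higher and 4 lower of 14 (0 and 8 adjusted over the list alone; camera adjusted p = 0.000297, lost with an estimated correlation at 0.430 and by fry at 0.0754). These were H2-DMb1 (-0.57), Ctss (-0.54), H2-Ob (-0.47) and Cd40 (-0.40). Inflammatory genes had 1 higher, Ptgs2 (0.28), and 6 lower of 20 (1 and 13 adjusted over the list alone; camera adjusted p = 0.000793, 0.409 with an estimated correlation). The lower included Nlrp3, Ccl4 (-0.42), Tnf (-0.32) and Osm (-0.28). Chemokine genes had 0 higher and 5 lower of 20 (1 and 6 adjusted over the list alone; camera adjusted p = 0.0216, 0.409 with an estimated correlation). They included Ccl6, Ccl9 (-0.50) and Ccl5 (-0.45). Other adhesion genes had 1 higher and 5 lower of 30 (1 and 13 adjusted over the list alone; camera adjusted p = 0.0252, 0.409 with an estimated correlation). Thbs1, Jaml (-0.52) and Icam4 (-0.41) were among the lower. Suppressive function genes had 1 higher and 3 lower of 24 (1 and 5 adjusted over the list alone; camera adjusted p = 0.0216, lost with an estimated correlation at 0.430 and by fry at 0.0702). The lower were Cybb (-0.29, but 0.0321 at its gene-end region), Lgals9 (-0.36) and Pdcd1lg2 (-0.26). Glucocorticoid-responsive genes had 0 higher and 4 lower of 15 (0 and 6 adjusted over the list alone; camera adjusted p = 0.0159, lost with an estimated correlation at 0.430 and by fry at 0.0702), Fkbp5 (-0.44) among them. AP-1 genes had 0 higher and 5 lower of 20 (2 and 9 adjusted over the list alone; camera adjusted p = 0.0138, 0.430 with an estimated correlation). They included Fosl2 (-0.32), Fosb (-0.26) and Fos (-0.25). Granulocyte markers had no called member (camera adjusted p = 0.106, 0.826 with an estimated correlation). T and NK cell markers had 0 of 12 members called and lay lower in males by fry (adjusted p = 0.0366), but not by camera (adjusted p = 0.340, 0.538 with an estimated correlation).

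Integrins Itgax (-0.44), Itgam (-0.36) and Itgal (-0.27) were lower and Itga7 (0.74) was higher in male mMDSC, while Itgb1 (0.17, adjusted p = 0.0573) and Dpp4 (0.12, adjusted p = 0.296) did not pass. Sex-linked genes had 4 higher and 8 lower of 12 (the same counts adjusted over the list alone; camera adjusted p = 0.0407, adjusted p = 0.538 with an estimated correlation); their median was -0.519 and their mean 1.89. Leaving out 1 library ended some list calls in mMDSC: other adhesion genes without female tumor 1 (0.0563), suppressive function genes (0.123) and chemokines (0.0915) without female tumor 2, and sex-linked genes without female tumor 1 (0.111), female tumor 2 (0.755) or male tumor 2 (0.102). Granulocyte markers became called, lower in males, without female sham 1 (0.0369) or female tumor 1 (1.43e-05).

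Whether sex acted differently in the cell types was tested directly, as a comparison added after seeing the data. By edgeR 6 regions differed (6700 at an unadjusted p under 0.05; DESeq2 5). The strongest, chrX:50565039-50565878 in Firre, was 3.05 log2 units less reduced in male mMDSC (-1.59) than in male gMDSC (-4.66; adjusted p = 0.000301). At the level of loci only Ftx, a non-coding RNA gene next to Xist, differed (0.73, adjusted p = 0.00807), with male minus female changes of -0.57 in mMDSC and -1.33 in gMDSC. The count of regions was 1 to 12 with 1 library left out: 12 without mMDSC female tumor 1, 3 without gMDSC female sham 1, gMDSC female sham 2, mMDSC female sham 1 or mMDSC male tumor 2, 2 without gMDSC female tumor 2, gMDSC male sham 2, gMDSC male tumor 1, gMDSC male tumor 2, mMDSC female sham 2, mMDSC male sham 1 or mMDSC male tumor 1, and 1 without mMDSC male sham 2. Ftx lost its call without gMDSC male sham 1 or gMDSC male sham 2, where 0 loci were called.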

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

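The tests of the 3 patterns weighed below, and the comparison of sex differences between the cell types, were chosen only after the results were seen, while the counts over other splits of the libraries were planned.

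Of 42 checks for a library far from the other 7 of its cell type, 2 passed, and chance alone passes about 5% of such checks. At the Arg1 locus, the arginase gene, mMDSC male sham 2 had 22.5 CPM, with the other mMDSC libraries between 26.1 and 29.1. At the Dpp4 locus, gMDSC male tumor 2 had 27.8 CPM, with the other gMDSC libraries between 38.6 and 45.7.

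Sex differences unlike between the cell types were found at 6 regions and 1 locus. On X, chrX:50565039-50565878 in Firre (difference 3.05 log2 units, mMDSC minus gMDSC) and chrX:152218517-152218994 in Iqsec2 (2.41; -0.67 in mMDSC and -3.10 in gMDSC) were lower in males of both cell types, more so in gMDSC. The same held for chrX:103621788-103623039 (0.77) and chrX:103616181-103617409 (0.73) in Ftx and for the Ftx locus (0.73). At chrX:140996479-140999280 in Atg4a the difference was 0.70, and at chr10:111190651-111190991 in Osbpl8 it was 2.44 (2.05 in mMDSC, -0.42 in gMDSC). Among 25 reassignments of sex within cell type and treatment, 3 called as many regions (6 with the real labels, at most 1363 with others) and 3 as many loci (1 and at most 2084), so chance was not excluded. The reassignment with 1363 regions exchanged the sexes in mMDSC alone and so added up the sex differences that the real labels subtract, a structure of the samples.

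By camera alone, lists differed between cell types in their sex difference: monocyte markers (adjusted p = 9.07e-05), inflammatory genes (6.67e-05), AP-1 genes (5.9e-05), chemokine genes (0.0144) and suppressive function genes (0.0470) lay lower in mMDSC relative to gMDSC, and erythroid markers (0.0480) and sex-linked genes (0.0183) higher. With an estimated correlation none of these 7 passed (adjusted p = 0.335 to 0.387). Monocyte markers also differed between cell types in their tumor difference by camera (0.000704), but not with an estimated correlation (0.617). By camera, in mMDSC the tumor difference of males lay below that of females for chemokine genes (0.00584), inflammatory genes (0.00400), AP-1 genes (0.00396), antigen presentation genes (0.0302) and interferon-stimulated genes (0.0440), and above it for sex-linked genes (0.00685). With an estimated correlation none of these 6 passed (0.472 to 0.704), and no member of them was called for sex by treatment. The 6 calls for sex by treatment in mMDSC numbered 0 without mMDSC male sham 2 and 2 without mMDSC female tumor 2. Single calls were also lost: interferon-stimulated genes without mMDSC female sham 1 (0.355), male sham 1 (0.156) or male tumor 2 (0.361), sex-linked genes without female sham 1 (0.808) or male tumor 2 (0.0835), antigen presentation genes without female sham 2 (0.363), female tumor 1 (0.0627) or male tumor 1 (0.635), and AP-1 genes without female tumor 1 (0.0611) or male tumor 1 (0.0822). The monocyte list call for cell type by treatment was lost without mMDSC male sham 2 (0.398).

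The first pattern weighed was the set of 944 autosomal regions called between the sexes in mMDSC, where the sex change of autosomal regions correlated with their mean level at -0.283 and with their cell type change at -0.262. A trend of signal with intensity was argued against as the whole cause, since with loess offsets 914 autosomal regions were called, 652 of them shared. The excess of calls lower in males was then nearly gone (453 higher, 461 lower), so such a trend may account for that excess. Thinning to equal totals left 907 calls, 628 of them shared (329 higher, 578 lower). The test already scales by totals, so thinning cannot remove a bias that goes with them. It therefore cannot decide on the larger totals of all female libraries. Granulocytic cells carried over into male mMDSC were weighed next. The share needed by regions lower in males (26.9% at their lower quartile) would raise the 8597 regions at least 2-fold higher in gMDSC by a median of 0.466. Their observed upper quartile was 0.383 (median 0.0801). That share came from regions called in this same comparison, where selection can enlarge changes, so the predicted rise may be too large and cannot decide. Regions at least 2-fold higher in mMDSC were lower, as carry-over needs (median -0.0869). Those higher in gMDSC did not exceed regions uncalled between cell types (0.0821), which argues against carry-over as the whole cause. Handling shared by the libraries of one sex cannot be told apart from sex, since each sex was tested in its own mice, and sums by sex and replicate number called 165 autosomal regions, 162 of them shared. Sex itself stays open, untested, and the set depends on single libraries: 212 regions without mMDSC female sham 1, 235 without female sham 2, 161 without male sham 1, 72 without male tumor 1, 1419 without female tumor 2 and 5014 without male sham 2. The excess of lower calls did too: more regions were higher without female sham 1 (129 higher, 83 lower), female sham 2 (130, 105), male sham 1 (96, 65) or male tumor 1 (43, 29). Lower calls stayed more numerous when any other mMDSC library was left out, as without male sham 2 (1231, 3783).

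The second pattern was a set of 8 autosomal regions at least 2-fold higher in males in both cell types, such as chr16:39052652-39052872 (5.20 in mMDSC and 6.00 in gMDSC), chr9:48217569-48217779 in Nxpe4 (4.37 and 3.04) and chr11:31922593-31922853 in Cpeb4 (3.89 and 3.51). They were 211 to 571 bp wide, with a median of 262 bp against 474 bp over all regions. Counting noise was argued against, because 11 regions were called higher in males in both cell types and independent lists would share 0.131. Reads from copies of these sequences on the Y chromosome may be placed there: the 15 other regions within 50 kb had a median change of 0.193 in mMDSC, none of them called, against 3.75 for the 8 regions themselves. Sequence was not available to search for such copies, and male regulation of these regions stays open.

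The third pattern was the gain in females across Firre, 4933407K13Rik and Xist. A second X chromosome read alike in all regions was argued against, because X regions outside these genes had medians of -0.131 in mMDSC and -0.226 in gMDSC. Tandem repeats present on 2 X chromosomes against 1 would lower males by 1 log2 unit, whereas the upper quartile inside the genes was -2.67 in mMDSC. As a hypothesis that was not tested, these genes may be open mainly on the inactive X of females.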

How the results depend on the processing

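Tests with counts thinned to equal totals, sums by sex and number, loess offsets, a block within sex, and the comparison of cell type by sex were added after seeing the data, and the other settings were planned. Among single loci 9621 values kept their side of the threshold, 390 lost the call, 107 gained it and 9 reversed. Among list results these were 2060, 126, 51 and 3. A change of direction was counted as reversed only where either fit called the value. Changes of direction among values never called are thus held in the first number. Of the counts of calls that answer a comparison, 341 stayed within 1.5 times and 95 did not; the cause was not tested. With the replicate number as a block, calls were 4293 regions and 3425 loci for sex in mMDSC, 356 regions for sex in gMDSC, and 1 region each for tumor in mMDSC and gMDSC (within each sex 12 and 4 regions, and 9 loci in gMDSC). The difference in log2 CPM between the number 1 and number 2 libraries of a group was correlated across regions with that of other groups. This correlation exceeded 0.1 in 5 of 28 group pairs (-0.119 to 0.267), but in 3 of the 4 pairs within a cell type and sex (0.0940 to 0.267), the strata of the tumor comparison. Whether the number marks a shared day is open. For sex in mMDSC DESeq2 called 419 regions, all 16 libraries 707 (757 loci), sums 310 (29 loci) and loess offsets 804 loci. For sex in gMDSC all 16 libraries gave 56 loci and gene-end regions 13. With RLE size factors 3 regions differed for cell type by sex, and DESeq2 called 4 loci.

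Called lists numbered 0 with an estimated correlation for cell type, cell type by treatment, and tumor, sex and sex by treatment. By fry they were 16 for cell type, 5 for sex in mMDSC and 0 otherwise, and on gene-end regions 3 for sex in mMDSC and 0 for cell type by treatment and tumor in gMDSC. Without 1 library or 1 replicate number, regions ranged over 50639 to 61924 for cell type (loci 10697 to 12096), 0 to 13 for tumor in mMDSC (loci 0 to 5), 0 to 20 for tumor in gMDSC (0 to 25), 207 to 6742 for sex in mMDSC (27 to 4799), 169 to 5968 for sex in gMDSC (26 to 5058), 1 to 12 for cell type by sex (0 to 6), and 0 to 1 for sex by treatment in each cell type. Lists ranged over 5 to 7 for cell type, 0 to 3 for cell type by treatment, 0 to 6, 6 to 10 and 0 to 7 for tumor, sex and sex by treatment in mMDSC, and 0 to 3, 1 to 4 and 0 to 2 in gMDSC. Within males, the tumor count in gMDSC ranged over 0 to 1, and within females in mMDSC over 0 to 9.

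Reversed on the gene-end region alone were Cd34 (0.79), Ebf1 (0.49), Klrb1c (0.98), Csf1r (-0.0099) and Nos2 (1.08) for cell type, and Pls3 (0.0812), Cybb (0.0321) and Sgk1 (0.0756) for sex in mMDSC. Ly6c2 reversed without replicate 2 for sex in gMDSC (-0.24 to 0.33 over the numbers left out). For granulocyte markers in mMDSC, the direction reversed for sex by treatment without female tumor 1 (adjusted p = 6.28e-05; 4.24e-06 to 0.792 over libraries) and for tumor without female tumor 2 (0.0230; 1.12e-08 to 0.856), and for antigen presentation genes in sex by treatment without male sham 2 (0.480; 3.73e-06 to 0.635). The peak difference was 17403, 15610 under the stricter threshold and 16024 to 18637 without 1 library. Tumor tests had a median 95% interval of ± 0.410 (mMDSC) and ± 0.509 (gMDSC) per region; the parts of depth and of variation between replicates were not separated.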

Other observations

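The test of a shared tumor response was chosen after the results were seen, and the counts over splits of the libraries were planned.

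Regions assigned to the same gene locus, inside or near the gene, did not always change in the same direction. Of 8602 loci with at least 3 tested regions, 4149 held called regions in both directions, 541 had every region called higher in mMDSC and 325 every region called lower. Over all regions 67.8% were called, 30722 higher and 30026 lower, so many mixed loci would arise by chance. The number expected by chance was not computed, so no pattern within genes is drawn from these counts. At Ccl2 all 9 regions were higher in mMDSC and at Batf3 9 of 12, whereas Arg1 had 3 higher and 1 lower of 5, and Cd163 had 2 higher and 8 lower of 11. Regions changed at least 2-fold lay away from gene ends: 55.6% of those higher in gMDSC and 46.8% of those higher in mMDSC lay outside genes, against 41.4% of uncalled regions.

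The 7 other X-linked genes of the sex-linked list had medians nearer 0 than Firre, 4933407K13Rik and Xist, with no test of the difference. In Kdm6a, a histone demethylase gene, 6 of 6 regions were lower in male mMDSC and 4 in male gMDSC (medians -1.31 and -1.37), and in Ftx 5 of 6 in each (-0.99 and -1.35). Kdm5c had 2 of 2 lower in each (-0.66 and -1.30), Eif2s3x 2 and 1 of 2 (-1.48 and -1.08), Jpx 1 of 1 in each (-0.56 and -0.86), Pbdc1 1 of 3 in each (-0.53 and -0.42) and Ddx3x 1 and 0 of 1 (-0.30 and -0.06). Of autosomal regions higher in female mMDSC, 80.1% were higher in mMDSC than in gMDSC, with a median cell type change of 0.69, and 87.7% changed in the same direction in gMDSC, where 139 of 568 had an unadjusted p under 0.05 by edgeR. For regions higher in male mMDSC these values were 38.0%, -0.18, 61.4% and 40 of 376.

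A tumor response shared by both cell types was tested through the correlation of tumor log2 fold changes across regions. It was 0.0198, and over 100 assignments 59 gave a value as large (others between -0.143 and 0.136), so no shared response was seen.

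Other splits of the same libraries, without the original design's other factors, were fitted for each comparison. For cell type, 1 of 25 splits, the real one, called as many regions (59049, with at most 0 in others) or loci (11917 and at most 0). The other splits mixed the cell types, so the cell type difference entered their residual variation and calls were hardly possible. This count therefore cannot decide on chance. For sex in mMDSC, 1 of 35 splits called as many regions (2907, at most 5 in others) and 1 of 35 as many loci (2982, at most 0). For sex in gMDSC, 1 of 35 did for regions (294, at most 265), but 2 of 35 for loci (50, at most 1539). The other splits mixed the sexes, so the sex difference entered their residual variation. Sex chromosomes also favored the real split, with 79 Y and 94 X regions among the 227 called in the main gMDSC fit. The counts for sex therefore cannot decide on chance in either cell type. The split with 1539 loci set 3 gMDSC female libraries and gMDSC male tumor 2 against the others, a structure of the samples. The comparisons with 0 calls were matched by every split: 35 of 35 for tumor in mMDSC (highest others 2907 regions and 2982 loci, the split by sex) and in gMDSC (294 and 1539), the same for sex by treatment, and 25 of 25 for cell type by treatment (398 and 737). Any split matches a count of 0, so these shares were fixed in advance and carry no information on chance.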
